A study of Homo sapiens with 12 samples.

How the data were processed

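The study measured polyA RNA of primary human pulmonary microvascular endothelial cells in 12 libraries, 1 for each of 3 donors in each of 4 groups. Cells were held in low-serum medium, pre-treated for 1 h with water or 10 µM Y-27632 (ROCKi) and then treated for 6 h with DMSO or 100 nM vinblastine. The labels give 0.1% DMSO for the DMSO groups and no DMSO percentage for the vinblastine groups.

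The deposited table holds signal values that the authors made from sequencing reads: gene counts divided by 1 size factor per library. The processing notes of the authors name Trim Galore 0.6.6, FastQC 0.12.1, Salmon 1.8.0, STAR 2.7.9a, DESeq2 1.44.0 and the genome build GRCh38. Their settings, the annotation, the strand setting and the way reads were counted are not given in the sources used here. The size factors were recovered here from the spacing of the values (0.841 to 1.29), and after multiplication 100% of the values were whole numbers within 0.01. The recovered reads may be Salmon estimates that were rounded before scaling. Depth was 17868046 to 24042745 recovered reads per library. Pairs of libraries of the same group differed by a chi-square of 67.5 to 155 per degree of freedom, so differences between donors, and not depth, set the precision. The sum of values was 18.8 ± 0.343, 21.4 ± 0.561, 18.7 ± 0.164 and 20.4 ± 0.372 M normalised reads in water with DMSO, water with vinblastine, ROCKi with DMSO and ROCKi with vinblastine (mean ± SD of 3). The 100 highest genes held 23.2, 25.5, 23.0 and 24.0% of it.

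The table has 38900 genes, 14591 of them at 0 in every library. Gene symbols came from the reference gene names, and locations, GC content and exon length from GENCODE 29. Genes with a mean of at least 10 were tested (14332, of which 13682 had a symbol). Values were analysed as log2(value + 1) in R 4.3.3 with limma 3.58.1 (mean-variance trend, robust moderation), with 1 mean per group and all 12 libraries in 1 fit. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. The 5 comparisons were vinblastine against DMSO after water and after ROCKi, ROCKi against water with DMSO and with vinblastine, and the difference between the 2 responses to vinblastine. Groups, comparisons, gene lists and the first set of alternatives were fixed before the data were examined. The fit has no donor term, and a fit with the donor as a block was set as an alternative at the same time. Its value is printed beside a result where it changes a call or moves a count by more than 1.5-fold. Gene adjusted p values are those of limma unless another tool is named. The median standard error of a change was 0.241 (0.144 with the donor block), and 0.341 (0.204) for the difference of responses.

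The labels give the donor of each library. As a check, the deviations of each library from its group mean had correlations of 0.675 to 0.79 between libraries of the same donor and of −0.467 to −0.209 between donors. Principal components 1 and 2 (36.8 and 26.7% of the variance) separated donors and component 3 (14.6%) vinblastine from DMSO.

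Named genes follow a rule. For vinblastine after water, ROCKi with DMSO and the difference of responses they are the 12 largest changes of each sign, and for the other comparisons the 5 largest. A gene qualified with an adjusted p under 0.05, the same sign in each of the 3 donors, a mean of at least 100 in the highest group compared and a symbol other than that of a clone or antisense RNA. The rule found 956 eligible genes after water, 496 after ROCKi and 0 for ROCKi with DMSO and for the difference. With fewer than 5 eligible genes the rule was applied to the fit with the donor block, as for ROCKi with vinblastine (199 eligible). Up to 4 members of each list that passed or had a called member, and a set of focal genes, could be named as well. A change on this scale understates that of genes with low values.

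There were 31 gene lists with 477 genes, of which 446 genes were tested, 30 were below the filter and 1 had no identifier. The 29 lists with at least 5 tested members were tested against all other genes with camera (preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison). They were tested again with a correlation estimated from the data, and with fry, which tests the direction of a list and not its difference from other genes. Members were counted with adjustment over all genes and over the list alone, the latter without the block unless it is named. Marker lists were summed as a rough guide to the cultures, and such sums of RNA do not give shares of cells. In water with DMSO endothelial identity genes had a summed level of 14500 ± 3380 RPM (reads scaled to a common library total, mean ± SD of 3). Lymphatic markers had 1690 ± 1110, fibroblast and mural markers 420 ± 425, epithelial markers 9.54 ± 2.14 and leukocyte markers 3.94 ± 1.20. The fibroblast and mural sum differed between donors by as much as its mean, so it does not describe each culture. The lymphatic sum also differed strongly between donors. Single genes held much of these sums: RELN had 957 RPM among lymphatic and RGS5 271 RPM among fibroblast and mural markers (means of all 12 libraries).

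The share of the response to vinblastine kept after ROCKi was measured per donor. The 150 highest and 150 lowest genes by moderated t after water were chosen in the other 2 donors, and the mean signed change after ROCKi was divided by that after water. The 3 differences were tested with an exact sign-flip test, whose smallest p is 0.25. Without a replicate, the share averages the other 2 donors, whose genes were still chosen with the left-out donor.

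The alternatives tried were pseudocounts of 5 and 0.1, no filter or a mean of at least 50, upper quartile scaling, the libraries compared alone, plain limma, a 2-fold threshold, and leaving out each replicate. For the kept share 50 or 500 genes of each sign, each sign alone and the genes called in all donors were tried. Chosen after seeing the data were total scaling, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads (with and without the donor block), the block combined with other choices, and the blocked fit without each replicate. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

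The steps were tested on simulated data with the same size and spread, in which 100 or 200 genes of each comparison were changed by 2-fold and as many by 4-fold. After water 34 and 71.5% of them were recovered (67 and 90.5% with the donor block, with 23 false calls of 338), for ROCKi with DMSO 34 and 58% (63 and 83%), after ROCKi 26 and 64% (65 and 85%) and for ROCKi with vinblastine 37.5 and 69% (66.5 and 90%). For the difference of responses 11 and 48% were recovered (47 and 84% with the donor block, with 6 false calls of 137). A simulated kept share of 50% was returned as 51 ± 1.39%. The simulated response was the same in each donor, so the SD of 1.39% leaves out differences in response between donors. Camera called 50 of 50 raised lists and 1 of 50 unchanged lists. Simulated genes varied independently and the lists were drawn at random. The simulation therefore cannot show how often camera with the preset correlation calls unchanged lists whose genes vary together.

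No library was left out. Reads of tubulins, actins, ribosomal proteins and mitochondrial genes may be shared with near-identical copies elsewhere in the genome, and the strand setting is unknown, so single values of these genes, and of genes that overlap others, are uncertain. XIST and Y-linked genes were left out of every table of single genes.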

Results

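Vinblastine breaks down microtubules, and Y-27632 (ROCKi below) inhibits the kinases ROCK1 and ROCK2. How far does ROCK inhibition alter the RNA response of lung microvascular endothelial cells to vinblastine? Cells of 3 donors received water or 10 µM Y-27632 for 1 h and then, for 6 h, vinblastine at 100 nM or DMSO at 0.1%. Each of the 4 groups had 3 libraries, 1 per donor, and 14332 genes were tested. Changes are on the log2 scale with the standard error of the limma fit, and levels are normalised reads, given as mean ± SD of 3 libraries.

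After water, vinblastine raised 12 of 21 tested genes of the NF-kB and inflammatory list, which code for adhesion molecules, chemokines and regulators of the pathway. CSF2, which codes for a growth factor of myeloid cells, rose by 4.33 ± 0.38 (20.1-fold, adjusted p = 0.000902), from 5.87 ± 1.96 to 137 ± 33.1 normalised reads. TRAF1, an adaptor of tumour necrosis factor receptors, rose by 4.14 ± 0.41 (adjusted p = 0.00104), from 517 ± 226 to 8656 ± 1632. The adhesion molecules SELE and VCAM1 rose by 4.08 ± 0.98 and 2.76 ± 0.60 (adjusted p = 0.0362 and 0.0255), and the chemokines CX3CL1 and CXCL8 by 4.20 ± 0.99 and 3.08 ± 0.57 (adjusted p = 0.0346 and 0.0128). NFKBIA, which codes for an inhibitor of NF-kB, rose by 1.53 ± 0.15 (adjusted p = 0.000975). In this list 0 genes fell (16 rose with adjustment over the list alone, and 18 with the donor block), and the median change was 2.23 (camera, adjusted p = 4.97e-13, and adjusted p = 0.144 with an estimated correlation). ICAM1 changed by 2.92 ± 0.86 and CCL2 by 2.14 ± 0.87, and these were not called (adjusted p = 0.0735 and 0.174, and 0.0157 and 0.015 with the donor block). Without replicate 3, 0 genes were called in the fit without the donor block, so each gene call of this paragraph was lost there. With the donor block 1924 genes were still called without replicate 3. Statements below on gene calls without a replicate refer to the fit without the block unless the block is named.

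**Figure D1:**
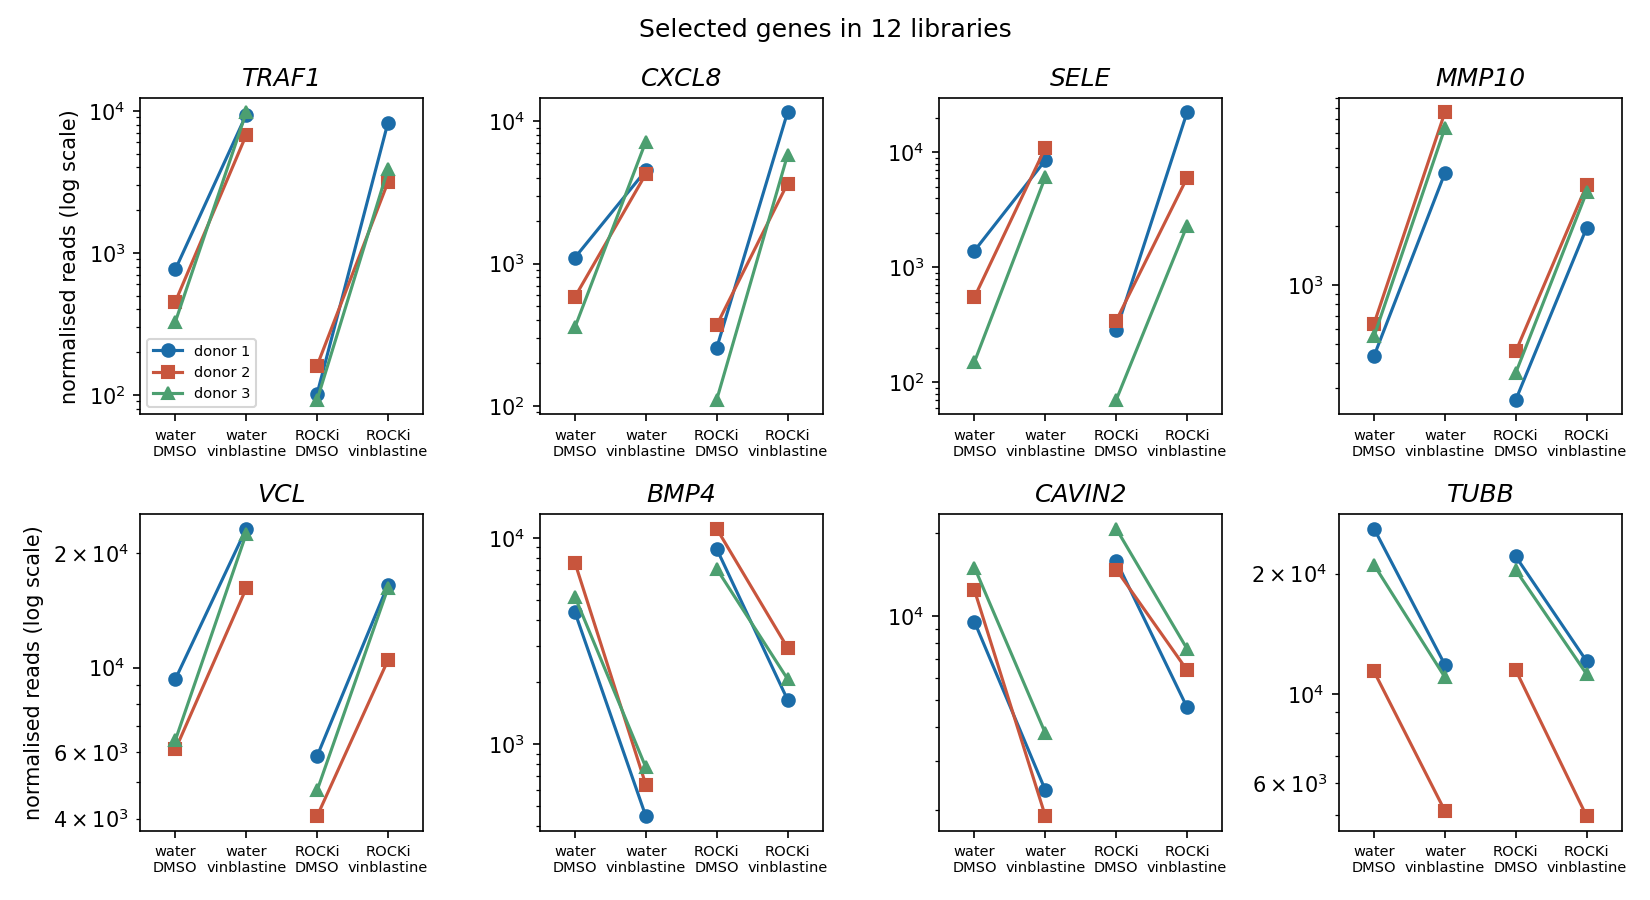
Normalised reads of 8 genes (vertical log axis) in the 4 groups of libraries; each point is 1 library, and a line joins the DMSO and vinblastine libraries of a donor within each pre-treatment. TRAF1 went from 517 to 8656 on average after water, BMP4 from 5716 to 619, and each donor moved in the same direction in both arms.

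Some genes that respond within hours to growth signals and stress also rose. ATF3 rose by 3.04 ± 0.60 (adjusted p = 0.0174), JUNB by 1.61 ± 0.27 (adjusted p = 0.00943) and KLF6 by 1.39 ± 0.25 (adjusted p = 0.0121). All 3 code for transcription factors. Of 20 tested immediate-early and AP-1 genes 11 rose and 0 fell (13 over the list alone, and 15 rose with the donor block), with a median of 1.28 (camera, adjusted p = 2.78e-09, and adjusted p = 0.144 with an estimated correlation). DUSP8 and DUSP10, phosphatases of MAP kinases, rose by 3.10 ± 0.70 and 3.05 ± 0.54 (adjusted p = 0.0282 and 0.0113). The call of DUSP8 was lost with a pseudocount of 0.1 (3.13, adjusted p = 0.175). With replicate 3 left out, 0 of these genes were called.

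Some targets of SRF and its actin-regulated cofactors (MRTF) rose, as did some genes of focal adhesions. VCL, which codes for vinculin, rose by 1.51 ± 0.24 (adjusted p = 0.00702), from 7284 ± 1778 to 20650 ± 3883 normalised reads. CALD1, PDLIM7 and ACTG1, which code for actin-binding proteins and a cytoplasmic actin, rose by 1.54 ± 0.24, 1.41 ± 0.19 and 0.77 ± 0.13 (adjusted p = 0.00639, 0.00352 and 0.00943). The integrin gene ITGAV rose by 1.13 ± 0.14 (adjusted p = 0.00287), and ILK and FERMT2, whose products bind integrin tails, by 1.05 ± 0.13 and 1.13 ± 0.21 (adjusted p = 0.00248 and 0.0141). Of 21 SRF-MRTF targets 11 rose and 0 fell (14 over the list alone, and 17 rose and 1 fell with the donor block), with a median of 0.77 (camera, adjusted p = 3.52e-09, and adjusted p = 0.276 with an estimated correlation). Of 18 focal adhesion genes 5 rose and 0 fell (8 over the list alone, and 11 rose with the donor block), with a median of 0.38 (camera, adjusted p = 6.04e-05, and adjusted p = 0.206 with an estimated correlation). These gene calls too were lost without replicate 3, with 0 left.

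Some genes of proteins that bind microtubules rose by smaller amounts, and the genes of the inhibited kinases were not called. RHOA changed by 0.02 ± 0.12 (adjusted p = 0.964) and ARHGEF2, which codes for a microtubule-bound exchange factor, by 0.14 ± 0.17 (adjusted p = 0.706). ROCK1 and ROCK2 changed by 0.21 ± 0.10 and 0.37 ± 0.18 (adjusted p = 0.229 and 0.26, and 0.027 and 0.00456 with the donor block). MAP1S, MAP4 and DYNC1H1, which code for microtubule-bound proteins and a motor, rose by 1.15 ± 0.12, 0.55 ± 0.08 and 0.80 ± 0.09 (adjusted p = 0.00126, 0.00462 and 0.00175). Of the 20 genes of this kind 5 rose and 0 fell (6 over the list alone, and 7 rose and 2 fell with the donor block), and the median was 0.07, −0.03 with upper quartile scaling and −0.12 with total scaling. The camera call of this list (adjusted p = 0.0311) was lost with an estimated correlation (adjusted p = 0.324 with an estimated correlation), with the donor block (adjusted p = 0.0694), with total scaling (0.057) and without replicate 2 (0.207). Without replicate 3, 0 genes of this paragraph were called.

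Of the tubulin genes, TUBB changed by −1.07 ± 0.47 (adjusted p = 0.206, and 2.58e-05 with the donor block) and TUBA1B by −1.01 ± 0.28 (adjusted p = 0.0597, and 0.00177 with the donor block), and reads of these genes may be shared with near-identical copies. TTC5, which codes for a factor that marks tubulin mRNA for decay, changed by −0.41 ± 0.16 (adjusted p = 0.157, and 0.069 with the donor block). Of 10 tubulin genes 0 rose and 0 fell (0 and 1 over the list alone, and 5 fell with the donor block), with a median of −0.36 (camera, adjusted p = 0.102, and 0.0277 with the donor block). The blocked call was lost too, at adjusted p = 0.259 with an estimated correlation.

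BMP4, a growth factor, fell by 3.20 ± 0.29 (adjusted p = 0.000975), from 5716 ± 1677 to 619 ± 163 normalised reads. MAP2K6, a kinase upstream of p38, fell (−3.13 ± 0.52, adjusted p = 0.00842), as did GIMAP7, a GTPase (−2.84 ± 0.32, adjusted p = 0.00175), and CAVIN2, a coat protein of caveolae (−2.24 ± 0.28, adjusted p = 0.00287). Of the S phase genes CCNE2, a cyclin, fell by 1.79 ± 0.27 (adjusted p = 0.00547). MCM2 and MCM3, subunits of the replicative helicase, fell (−0.73 ± 0.16 and −0.54 ± 0.11; adjusted p = 0.0237 and 0.0225), as did PCNA, the clamp of DNA polymerase (−0.72 ± 0.18, adjusted p = 0.043). Of 18 genes of that list 4 fell and 0 rose (7 fell over the list alone, and 13 with the donor block), with a median of −0.61 (camera, adjusted p = 1.95e-06, and adjusted p = 0.324 with an estimated correlation). Without replicate 3 these calls were lost, with 0 genes called.

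MMP10, which codes for a matrix protease, rose by 3.40 ± 0.31 (adjusted p = 0.000975). CLDN14 (3.85, adjusted p = 0.011), NOD2 (3.45, 0.0385), SPOCD1 (3.12, 0.00685) and STC1 (3.11, 0.0192) rose too. GALNT15 (−2.43, 0.0441), GCNT1 (−2.34, 0.00769), ELMOD1 (−2.15, 0.0143), SPIN4 (−2.10, 0.0079), RUNX1T1 (−2.10, 0.0272), LMCD1 (−2.08, 0.0114), FAM110D (−2.06, 0.00515) and RIMS1 (−2.05, 0.0443) fell. Without replicate 3, 0 of them were called.

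Mitochondrially encoded RNA was higher and mRNA of ribosomal proteins lower, by small amounts. MT-ND4L, a subunit of complex I, rose by 0.50 ± 0.12 (adjusted p = 0.0374; 0.0897 with upper quartile and 0.163 with total scaling). Of 13 mitochondrial genes 1 rose and 0 fell (8 over the list alone, and 13 rose with the donor block), with a median of 0.41 (camera, adjusted p = 1.01e-05, and adjusted p = 0.363 with an estimated correlation). RPS14 and RPL11 changed by −0.29 ± 0.08 and −0.24 ± 0.07 (adjusted p = 0.0501 and 0.0785, and 0.00452 and 0.00986 with the donor block). Of 20 ribosomal protein genes 0 rose and 0 fell (6 fell over the list alone, and 17 with the donor block), with a median of −0.22 (camera, adjusted p = 1.05e-06, and adjusted p = 0.276 with an estimated correlation). Ribosomal protein genes have many near-identical copies, so their single values are uncertain. Without replicate 3 MT-ND4L was not called, like all other genes.

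Of the tip cell genes VEGFC and ESM1, which code for a growth factor and a secreted proteoglycan, rose by 1.75 ± 0.35 and 1.53 ± 0.27 (adjusted p = 0.0185 and 0.0117). In that list 3 of 16 genes rose and 0 fell (3 over the list alone, and 8 rose and 1 fell with the donor block), with a median of 0.60 (camera, adjusted p = 0.0311, and adjusted p = 0.324 with an estimated correlation; 0.167 without replicate 2). TRIB3 and PPP1R15A, targets of ATF4 in the stress response, rose by 1.72 ± 0.20 and 0.88 ± 0.13 (adjusted p = 0.00175 and 0.00486). Of 18 ATF4 and unfolded protein genes 3 rose and 0 fell (3 and 1 over the list alone, and 5 rose and 2 fell with the donor block), with a median of 0.25 (camera, adjusted p = 0.0345, and adjusted p = 0.391 with an estimated correlation; 0.462 without replicate 2). Without replicate 3 the 4 genes named here were not called, with 0 calls in all.

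Other focal genes of endothelial function were not called. KLF4, a flow-responsive factor, changed by 2.99 ± 1.06 (adjusted p = 0.123, and 0.000263 with the donor block), and KLF2 by 0.44 ± 0.63 (adjusted p = 0.76). NOS3, which makes nitric oxide, changed by −1.56 ± 0.45 (adjusted p = 0.068, and 1.8e-05 with the donor block) and EDN1, a vasoconstrictor, by −0.74 ± 0.30 (adjusted p = 0.175, and 0.00373 with the donor block). THBD changed by −0.02 ± 0.51 (adjusted p = 0.991) and RHOB by 0.20 ± 0.28 (adjusted p = 0.751). The YAP-TEAD targets CCN1, CCN2 and ANKRD1 changed by 0.55 ± 0.15, −0.49 ± 0.31 and 0.84 ± 0.30 (adjusted p = 0.0574, 0.398 and 0.128, and 0.000405, 0.0176 and 0.0398 with the donor block). ACTA2, a smooth muscle actin, changed by −0.42 ± 0.48 (adjusted p = 0.681, and 0.0175 with the donor block). Of these genes ANKRD1 was called without replicate 2 (adjusted p = 0.0214).

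The following lists did not pass their test after water. With 1 gene that rose and 0 that fell, YAP-TEAD targets had a median of 0.27 (camera, adjusted p = 0.102), endothelial junctions 0.22 (0.242), matrix and TGF-beta genes 0.39 (0.163, and 0.0217 with the donor block) and hypoxia and glycolysis genes 0.04 (0.315). With 2 that rose and 0 that fell, NRF2 targets had a median of 0.08 (0.172), heat shock genes 0.01 (0.291) and vasoactive and haemostatic genes −0.28 (0.864), the mean of the last being 0.27. With 0 that rose and 1 that fell, endothelial identity genes had a median of −0.15 (0.465), interferon genes −0.18 (0.788), cholesterol synthesis genes −0.02 (0.788) and BMP-ID genes −0.36 (0.102, and 0.0358 with the donor block). The blocked calls of matrix and BMP-ID genes were lost at adjusted p = 0.263 and 0.288 with an estimated correlation. Among p53 targets 3 rose and 1 fell (median −0.09, mean 0.05; 0.864). In 5 lists 0 genes were called: Notch (median −0.20, mean 0.14; 0.816), KLF2-KLF4 (−0.16, 0.864), mitosis (0.18, 0.172), lymphatic markers (0.26, 0.922) and fibroblast and mural markers (−0.43, 0.291). Epithelial and leukocyte markers had 2 and 3 genes above the filter, too few for a list test, and 0 of them were called (1 leukocyte marker rose with the donor block). Over the list alone the counts that differed were 2 that rose in YAP-TEAD targets, 2 in junctions, 3 in hypoxia genes, 4 in vasoactive genes (with 1 that fell) and 1 in cholesterol genes, and 2 that fell in BMP-ID genes and 1 in fibroblast and mural markers. With the donor block the counts that rose and fell were 6 and 3 for YAP-TEAD targets, 5 and 1 for junctions, 7 and 3 for matrix genes, 4 and 1 for hypoxia genes, 6 and 1 for NRF2 targets, 4 and 0 for heat shock genes and 5 and 8 for vasoactive genes. They were 3 and 5 for endothelial identity, 2 and 3 for interferon genes, 2 and 3 for cholesterol genes, 1 and 6 for BMP-ID genes, 4 and 7 for p53 targets, 4 and 1 for Notch, 2 and 3 for KLF2-KLF4, 2 and 0 for mitosis, 3 and 1 for lymphatic and 0 and 2 for fibroblast and mural markers.

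In total 1005 of 14332 genes changed after water (limma, no donor block), 638 higher (63.5%) and 367 lower, and 341 of them by at least 2-fold. With upper quartile scaling the counts were 491 and 706 (41.0% higher) and with total scaling 400 and 1315, because the median change of all genes went from −0.02 to −0.12 and −0.21. Directions of single lists are therefore to be read against these medians. With the donor block 4554 genes were called (2347 higher, 2207 lower). Without replicate 1, 2 or 3 the count was 97, 300 or 0 (2613, 3468 or 1924 with the donor block).

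With DMSO, levels of most NF-kB and inflammatory genes and SRF-MRTF targets were lower with ROCKi than with water, and limma called 0 of them. TRAF1 changed by −2.07 ± 0.41, CXCL8 by −1.49 ± 0.57 and VCAM1 by −1.39 ± 0.60, and CSF2 by −1.85 ± 0.38 (limma, adjusted p = 1 for each). CSF2 had 3 reads in the 3 ROCKi libraries with DMSO and 21 in those with water, a ratio of 6.87 for water over ROCKi (95% counting interval 2.05 to 36). The SRF-MRTF targets ZYX, PDLIM7 and VCL changed by −0.68 ± 0.26, −0.63 ± 0.19 and −0.57 ± 0.24. ACTA2, on the same list, went the other way, from 514 ± 218 with water to 565 ± 205 normalised reads with ROCKi. TUBA1A and TUBB2A, tubulin genes, changed by −0.52 ± 0.17 and −0.58 ± 0.32. The focal genes RHOA, ROCK1, NOS3 and KLF2 changed by 0.12 ± 0.12, 0.12 ± 0.10, 0.01 ± 0.45 and −0.07 ± 0.63.

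By list, 21 of 21 NF-kB genes were lower with ROCKi (median −0.70; 2 fell over the list alone), as were 19 of 21 SRF-MRTF targets (−0.33), 19 of 20 immediate-early genes (−0.37) and 9 of 10 tubulin genes (−0.28). Their camera tests gave adjusted p = 5.31e-13, 2.87e-10, 3.63e-07 and 0.00011 (adjusted p = 0.143, 0.211, 0.143 and 0.143 with an estimated correlation). Lower as well were focal adhesion genes (−0.08, adjusted p = 0.00111), ATF4 and unfolded protein genes (−0.19, 0.00177) and heat shock genes (−0.19, 0.00559), with adjusted p = 0.211, 0.246 and 0.244 with an estimated correlation. Higher were ribosomal protein genes (0.14, adjusted p = 2.56e-13), S phase genes (0.14, 0.00818), cholesterol synthesis genes (0.12, 0.0158) and mitosis genes (0.13, 0.0208), with adjusted p = 0.143, 0.714, 0.714 and 0.791 with an estimated correlation. Without replicate 2 the last 3 lists lost their call (adjusted p = 0.0758, 0.802 and 0.556). With the donor block Notch genes (−0.37, adjusted p = 0.00473), matrix and TGF-beta genes (−0.13, 0.0301) and mitochondrial genes (−0.07, 0.00887) passed too, and were lost at adjusted p = 0.592, 0.335 and 0.624 with an estimated correlation. With the block and adjustment over the list alone 14 SRF-MRTF targets, 6 focal adhesion, 3 immediate-early, 2 tubulin and 2 matrix genes fell and 1 matrix gene rose. In these lists 0 genes were called over all genes.

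In the comparison of ROCKi with water under DMSO, limma called 0 genes, with or without the donor block. With the donor block 1184 genes had an unadjusted limma p under 0.05, against 717 expected by chance. Without the block 259 had one. That fit keeps the differences between donors in its error, so its count below 717 does not show less change than chance. On the recovered reads edgeR called 0, DESeq2 10 and DESeq2 with the donor block 165.

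After ROCKi, vinblastine again raised 12 of 21 NF-kB and inflammatory genes. CXCL8 rose by 4.84 ± 0.57 (28.6-fold, adjusted p = 0.0027), from 245 ± 130 to 7009 ± 4100 normalised reads, TRAF1 by 5.33 ± 0.41 (adjusted p = 0.000351), SELE by 5.14 ± 0.98 (adjusted p = 0.022), CX3CL1 by 4.94 ± 0.99 (adjusted p = 0.0278) and VCAM1 by 3.72 ± 0.60 (adjusted p = 0.0108). CSF2 rose by 6.09 ± 0.38 (adjusted p = 0.000146), and its 426 reads against 3 give a ratio of 153 (95% counting interval 51.8 to 742). DUSP8 rose by 6.81 ± 0.70 (adjusted p = 0.00141), a size that depends on the pseudocount, since it was at 0 in 1 ROCKi library with DMSO. ICAM1 changed by 3.64 ± 0.86 (adjusted p = 0.0507, and 0.00893 with the donor block). In this list 0 fell (20 rose over the list alone, and 20 with the donor block), with a median of 2.81 (camera, adjusted p = 8.7e-22, and adjusted p = 0.0704 with an estimated correlation). Without replicate 1, CSF2 and TRAF1 kept their calls among these genes, and without replicate 3, 0 genes were called (1238 with the donor block).

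ATF3 and KLF6 rose by 3.97 ± 0.60 and 1.55 ± 0.25 (adjusted p = 0.00882 and 0.0108), and 9 of 20 immediate-early genes rose and 0 fell (12 over the list alone, 14 with the donor block, median 1.12, camera adjusted p = 8.62e-10, and adjusted p = 0.0962 with an estimated correlation). VCL, PDLIM7 and CALD1 rose by 1.55 ± 0.24, 1.25 ± 0.19 and 1.21 ± 0.24 (adjusted p = 0.00939, 0.00882 and 0.0247), as did 8 of 21 SRF-MRTF targets, with 0 that fell (14 over the list alone, 16 with the donor block, median 0.70, camera adjusted p = 8.22e-10, and adjusted p = 0.267 with an estimated correlation). ILK and ITGAV rose by 1.06 ± 0.13 and 0.92 ± 0.14 (adjusted p = 0.00317 and 0.00939), and 5 of 18 focal adhesion genes rose and 0 fell (5 over the list alone, 10 rose and 1 fell with the donor block, median 0.24, camera adjusted p = 0.000381, and adjusted p = 0.229 with an estimated correlation). The YAP-TEAD targets ANKRD1 and LATS2 rose by 1.49 ± 0.30 and 1.15 ± 0.20 (adjusted p = 0.0288 and 0.0151), the 2 genes called of 21 (6 over the list alone, 10 rose and 2 fell with the donor block, median 0.42, camera adjusted p = 0.00814, and adjusted p = 0.215 with an estimated correlation). Without replicate 3, 0 of these genes were called.

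BMP4 fell by 2.04 ± 0.29 after ROCKi (adjusted p = 0.00711), from 9017 ± 2005 to 2219 ± 659 normalised reads. GCNT1, MAP2K6, RUNX1T1, GIMAP7 and LMCD1 fell as well (−3.18 ± 0.38, −2.7 ± 0.52, −2.37 ± 0.47, −2.09 ± 0.32 and −2.06 ± 0.37; adjusted p = 0.00305, 0.022, 0.0247, 0.00883 and 0.0175). MCM3 fell by 0.59 ± 0.11 (adjusted p = 0.0236), the 1 S phase gene called of 18 (5 fell over the list alone, 10 with the donor block, median −0.48, camera adjusted p = 3.63e-06, and adjusted p = 0.35 with an estimated correlation). TUBB and TUBA1B changed by −0.98 ± 0.47 and −1.0 ± 0.28 (adjusted p = 0.329 and 0.0876, and 5.07e-05 and 0.00268 with the donor block) and NOS3 by −1.22 ± 0.45 (adjusted p = 0.192, and 7.98e-05 with the donor block). Ribosomal protein genes had a median of −0.16 with 0 called, and 4 that fell with the donor block (camera, adjusted p = 4.63e-05, and adjusted p = 0.35 with an estimated correlation) and mitochondrial genes of 0.20 with 0 called, and 10 that rose with the donor block (camera, adjusted p = 0.00814, and adjusted p = 0.698 with an estimated correlation; 0.0597 with total scaling). Tubulin genes had a median of −0.03 with 0 called (camera, adjusted p = 0.752, and 2 rose and 4 fell with the donor block) and matrix and TGF-beta genes of 0.31 with 1 that rose (0.225, and 0.0341 with 8 that rose and 1 that fell with the donor block, lost at adjusted p = 0.346 with an estimated correlation). Microtubule-binding proteins (median 0.01), tip cell genes (0.12) and ATF4 and unfolded protein genes (0.16) did not pass (camera, adjusted p = 0.0642, 0.157 and 0.108). In them 4, 2 and 3 genes rose and 0, 0 and 1 fell, and with the donor block 8, 4 and 4 rose and 2, 0 and 3 fell. Without replicate 1 GCNT1 kept its call, and without replicate 3 the calls of this paragraph were lost, with 0 genes called.

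**Figure D2:**
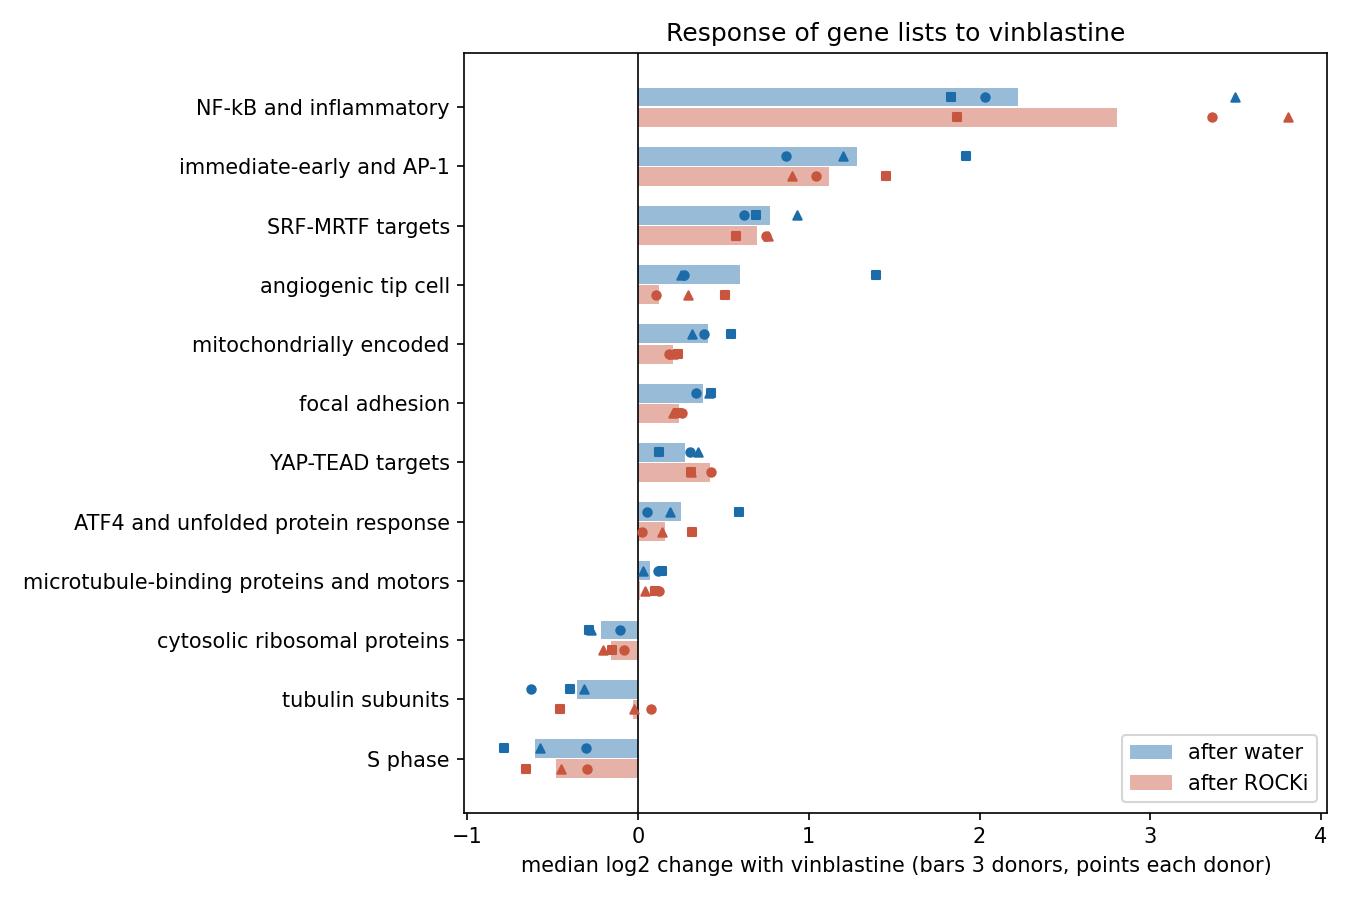
Median log2 change with vinblastine (horizontal axis) of 12 gene lists after water and after ROCKi; bars are the medians of the fit of 3 donors and points the medians of single donors (circle, square and triangle for donors 1, 2 and 3). The NF-kB and inflammatory list had a median of 2.23 after water and 2.81 after ROCKi, and S phase genes had −0.61 and −0.48.

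After ROCKi 523 genes changed with vinblastine (limma, no donor block), 393 higher (75.1%) and 130 lower, and 3206 with the donor block (1825 higher, 1381 lower). Without replicate 1, 2 or 3 the count was 9, 263 or 0 (1045, 2690 or 1238 with the donor block). Upper quartile scaling gave 294 higher and 207 lower (58.7% higher) and total scaling 257 and 278 (48.0%), with a median change of all genes of −0.10 and −0.14 against −0.02 as deposited. Of the genes higher after ROCKi 333 were also higher after water, against 17.5 expected of unrelated sets, and of the lower ones 106 against 3.33, and 0 genes were called in opposite directions. In the blocked fit 1524 were higher in both arms (299 expected) and 1106 lower in both (213 expected), and 2 genes were called in opposite directions. These 2 comparisons have no library in common, but they share the donors and, for each gene, the error of 1 fit. Genes with a small error are called more easily in both arms. The expected counts leave this out, so the overlap cannot be judged against them. Of the genes called after water without the block, 99.53% of the higher and 100% of the lower had the same sign after ROCKi.

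How much of the response remained under ROCK inhibition was measured in each donor on 300 genes chosen in the other 2 donors. CXCL8, VCL and BMP4, for example, were called in both arms, in the same direction. The mean signed change was 1.07 ± 0.01 after water and 0.95 ± 0.18 after ROCKi (mean ± SD of 3 donors), and 88.2 ± 16.4% of the response was kept (107, 79.6 and 77.8% in donors 1, 2 and 3). The exact sign-flip p was 0.5, where 3 donors allow no value under 0.25. Genes that rose kept 93.9 ± 15.0% and genes that fell 80.4 ± 20.2%. All these genes were chosen by their response after water. This choice can lower the share even where both responses are equally large over all genes. The reverse choice, by the response after ROCKi, was not run.

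**Figure D3:**
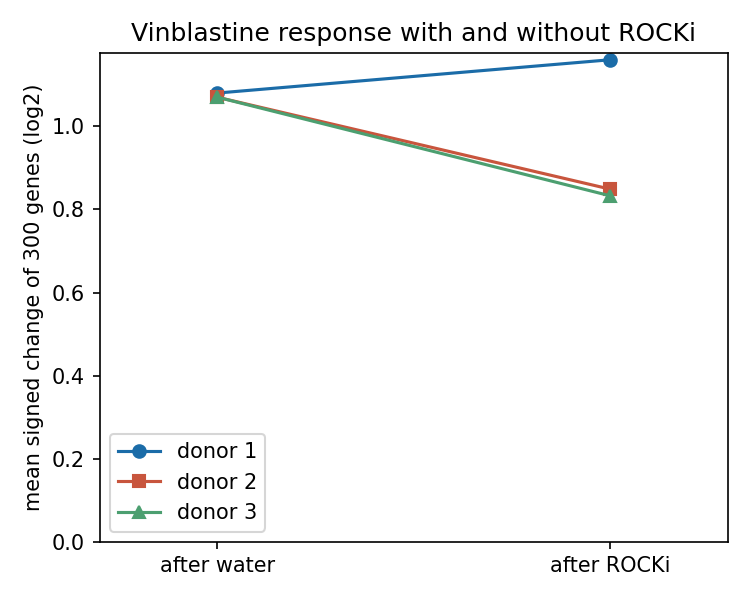
Mean signed log2 change with vinblastine of 300 genes chosen in the other donors (vertical axis), after water and after ROCKi; each line is 1 donor. In donors 2 and 3 the response after ROCKi was 79.6 and 77.8% of that after water, and in donor 1 it was 107%.

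In the difference between the 2 responses to vinblastine, no single gene passed with limma. CXCL8, which attracts neutrophils, had a response larger by 1.76 ± 0.80 after ROCKi, CSF2 by 1.76 ± 0.54, TRAF1 by 1.20 ± 0.57 and SELE by 1.06 ± 1.38 (limma, adjusted p = 1 for each). The value of CSF2 rests on its 3 reads in the ROCKi libraries with DMSO. The tubulin genes TUBA1A and TUBB2A had differences of 0.54 ± 0.24 and 0.47 ± 0.45, while TUBB and TUBA1B had 0.09 ± 0.67 and 0.01 ± 0.39. MT-CO1 and MT-ND5, of complexes IV and I, had −0.21 ± 0.19 and −0.22 ± 0.17.

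By list, 19 of 21 NF-kB genes had the larger response after ROCKi (median 0.74, camera adjusted p = 3.04e-05), a call lost without replicate 1 (adjusted p = 0.389). This larger response began from a lower level. With ROCKi against water the list median was −0.70 with DMSO and −0.21 under vinblastine. Of the mitochondrial genes 13 of 13 had the smaller response (−0.20, adjusted p = 0.000174). The change of tubulin genes was shifted upward after ROCKi in 10 of 10 (0.28, adjusted p = 0.0449; 0.337 without replicate 1 and 0.0653 without replicate 3) and that of ribosomal protein genes in 18 of 20 (0.06, adjusted p = 0.0449; 0.806 without replicate 2 and 0.306 without replicate 3). Each of the 4 was lost with an estimated correlation (adjusted p = 0.996 with an estimated correlation). With the donor block focal adhesion genes (−0.10, 0.0133) and hypoxia and glycolysis genes (−0.12, 0.0292) passed too, and were lost at adjusted p = 0.608 and 0.394 with an estimated correlation. In these lists 0 genes were called over all genes, and over the list alone 3 mitochondrial genes fell and 1 tubulin gene rose with the donor block, against 0 without it.

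For this difference limma called 0 genes, and 125 had an unadjusted p under 0.05 (774 with the donor block, smallest adjusted p = 0.0515). On the recovered reads edgeR called 0, edgeR with the donor block 1, DESeq2 4 and DESeq2 with the donor block 58. In simulated data the fit recovered 11% of genes whose response differed by 2-fold and 48% of those with 4-fold (47 and 84% with the donor block), so differences of this size could be missed.

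Under vinblastine, limma called BMP4 higher and some SRF-MRTF targets and focal adhesion genes lower with ROCKi in the donor-blocked fit alone. ACTA2, also on the SRF-MRTF list, went the other way, from 394.9 ± 202.1 with water to 451.8 ± 166.5 normalised reads with ROCKi. BMP4 changed by 1.83 ± 0.29 (adjusted p = 0.448, and 0.00568 with the donor block), from 619 ± 163 to 2219 ± 659 normalised reads, and MMP10 by −1.08 ± 0.31 (adjusted p = 0.747, and 0.0023 with the donor block), from 5888 ± 1974 to 2725 ± 674. PDLIM7, ITGAV, SRF and VCL changed by −0.79 ± 0.19, −0.64 ± 0.14, −0.54 ± 0.18 and −0.53 ± 0.24 (adjusted p = 0.696, 0.646, 0.765 and 0.845, and 0.014, 0.0108, 0.0409 and 0.0403 with the donor block). MAP3K14, a kinase that activates NF-kB, changed by −3.02 ± 0.96 (adjusted p = 0.765, and 0.041 with the donor block), while CXCL8 changed by 0.27 ± 0.57 (adjusted p = 1). By the same rule in the blocked fit came B3GALT2 (1.86, and adjusted p = 0.0289 with the donor block), GDF7 (1.75, 0.00925), SLC2A12 (1.68, 0.00839), SHISA3 (1.43, 0.0452; 1 library at 0), PDGFA (−1.02, 0.0484), ANGPTL4 (−1.45, 0.0294) and SPOCD1 (−1.63, 0.014).

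Ribosomal protein genes were higher with ROCKi under vinblastine (median 0.22, camera adjusted p = 3.43e-14), as were cholesterol synthesis genes (0.25, 0.000244; 0.0958 without replicate 1) and S phase genes (0.17, 0.00164), with adjusted p = 0.267, 0.417 and 0.526 with an estimated correlation. Lower were SRF-MRTF targets (−0.43, adjusted p = 1.04e-08), mitochondrial genes (−0.26, 7.74e-07), immediate-early genes (−0.45, 2.07e-05) and focal adhesion genes (−0.25, 6.42e-05), with adjusted p = 0.392, 0.401, 0.295 and 0.29 with an estimated correlation. Lower as well were ATF4 and unfolded protein genes (−0.23, adjusted p = 0.00164) and heat shock genes (−0.17, 0.026; 0.185 without replicate 2, 0.0647 without replicate 3 and 0.0514 with total scaling), with adjusted p = 0.392 and 0.401 with an estimated correlation. In the blocked fit 8 SRF-MRTF targets, 6 mitochondrial, 5 focal adhesion, 2 matrix genes and 1 Notch gene fell and 2 ribosomal protein genes and CCNE2 rose, against 0 without it. Over the list alone 1 SRF-MRTF target and 1 focal adhesion gene fell and 1 S phase and 1 cholesterol synthesis gene rose. With the block these counts over the list alone were 17 SRF-MRTF targets (1 more rose), 12 mitochondrial, 10 focal adhesion, 4 immediate-early, 3 heat shock, 2 ATF4, 4 matrix, 3 tip cell (1 more rose) and 2 Notch genes that fell, and 17 ribosomal protein genes, 1 S phase and 1 cholesterol synthesis gene that rose. Tip cell (−0.21, 0.0148), Notch (−0.23, 0.0112) and matrix genes (−0.20, 0.012) passed with the donor block as well, and were lost at adjusted p = 0.363, 0.485 and 0.278 with an estimated correlation. NF-kB genes did not pass (−0.21, adjusted p = 0.236).

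Of 14332 genes limma called 0 in this comparison, with 836 at an unadjusted p under 0.05, and with the donor block 208 (85 higher, 123 lower; 2670 at an unadjusted p under 0.05). The blocked count was 1, 8 or 1 without replicate 1, 2 or 3. On the recovered reads edgeR called 0, edgeR with the donor block 182, DESeq2 68 and DESeq2 with the donor block 934.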

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

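The tests of the NF-kB and tubulin lists for low values, scaling, single donors and shared reads were chosen only after the result was seen, and the splits of libraries were planned before.

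NF-kB and inflammatory genes had a larger response to vinblastine after ROCKi (median difference 0.741, 19 of 21 genes higher, adjusted p = 3.04e-05, and adjusted p = 0.996 with an estimated correlation). If low values made this, a pseudocount of 5 would bring the median under 0.5 of its size, and it stayed at 0.726, which excludes that explanation. The test of library scaling cannot decide. The list median, not centred on other genes, was 0.758 with upper quartile and 0.804 with total scaling. Both scalings raised the median difference of all genes, from 0.012 to 0.029 and 0.073, so they could only raise that of the list. Under each scaling the list median stayed above that of all genes. A single donor fits as the source: without replicate 1 the median was 0.175 and its adjusted p 0.389, against 1.16 (1.11e-08) without replicate 2 and 0.99 (2.07e-06) without replicate 3. Most of the pattern may thus come from donor 1, and 3 donors cannot tell a trait of that donor from chance. The larger response went with a lower starting level. With ROCKi against water the list median was −0.702 with DMSO and −0.21 under vinblastine (camera, adjusted p = 0.236 for the latter). On the median, levels under vinblastine were thus not higher with ROCKi.

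In the fit with the donor block TUBB and TUBA1B fell with vinblastine in both arms, by 1.07 and 1.01 after water and 0.98 and 1.00 after ROCKi. If reads moved between near-identical copies, summed alpha and summed beta tubulin values would keep their level, but they changed by −0.327 to −0.777 over the donors and arms, and copies below the filter held at most 0.131% of a sum, which excludes such moves as the whole cause. The test of scaling cannot decide. Not centred on other genes, the smallest mean fall of a sum was −0.443 over 3 scalings and both arms. Upper quartile and total scaling lowered the median change of all genes (−0.12 and −0.205 after water against −0.022). They could thus only deepen a fall. Less the median change of all genes, the mean changes of the sums were −0.424 to −0.635, so the sums fell more than the median gene. The sum of alpha tubulins changed by −0.65 ± 0.18 after water and −0.47 ± 0.23 after ROCKi and that of beta tubulins by −0.50 ± 0.13 and −0.44 ± 0.13 (mean ± SD of 3 donors). The 5 beta tubulin genes other than TUBB had a median change of 0.144 after water and 0.44 after ROCKi. In the blocked fit 0 of them rose and 1 fell after water, and 2 rose and 1 fell after ROCKi. The fall of the beta sum thus does not hold for most of its genes. The 5 alpha tubulin genes had medians of −0.445 and −0.209. Tubulin mRNA is known to decay when free tubulin rises. Whether this caused the fall of the sums was not tested, and free tubulin was not measured here.

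Between the responses tubulin genes had a median difference of 0.276 (10 of 10 genes higher, adjusted p = 0.0449, and adjusted p = 0.996 with an estimated correlation). The camera call was lost without replicate 1 (median 0.175, adjusted p = 0.337) and replicate 3 (median 0.275, adjusted p = 0.0653). Without replicate 3 the median thus kept its size. With ROCKi against water the list median was −0.28 with DMSO and −0.024 under vinblastine. The sums differed by 0.180 ± 0.199 (alpha) and 0.059 ± 0.177 (beta, mean ± SD of 3 donors), so shared reads and a single donor stay open for this difference.

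Mitochondrially encoded genes had a median difference of −0.198 (13 of 13 lower, adjusted p = 0.000174, and adjusted p = 0.996 with an estimated correlation). It was −0.181 with upper quartile and −0.136 with total scaling and −0.144 to −0.244 without 1 replicate (adjusted p = 1.48e-06 to 0.0315). Ribosomal protein genes had a median difference of 0.062 (18 of 20 higher, adjusted p = 0.0449, and adjusted p = 0.996 with an estimated correlation), which was 0.079 with upper quartile and 0.124 with total scaling. Its camera call was lost without replicate 2 (median 0.023, adjusted p = 0.806) and replicate 3 (median 0.079, adjusted p = 0.306). The median shrank without replicate 2 alone, so a single donor, by these medians donor 2, stays open as its source. Other explanations were not tested for these lists.

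Each comparison was repeated with the libraries split in the 10 possible ways into 2 sets of 3, which are too few for a share under 0.05 (lowest 0.1). After water the real split gave 1005 genes and the highest other 0, so 1 of 10 splits was as large. After ROCKi these were 523 and 1, again 1 of 10. For ROCKi with DMSO, the difference of responses and ROCKi with vinblastine the real split gave 0 and the highest other 1. With a real count of 0 every split is as large (10 of 10) whatever the data, so this tells nothing about these comparisons. Among the 4 splits that part all 3 pairs, the real one included, the highest other gave 0, 1, 0, 0 and 1 genes in the order of vinblastine after water, ROCKi with DMSO, vinblastine after ROCKi, the difference and ROCKi with vinblastine. With the donor block the real counts were 4554, 0, 3206, 0 and 208 and the highest others 0, 1, 0, 1 and 1. Every split other than the real one mixes the groups or arms compared. A real response then enters the error of that split and lowers its count. The low counts of the other splits thus do not show what would be called without a response.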

How the results depend on the processing

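The tests with total scaling, edgeR, DESeq2, the block combined with other choices and the blocked fit without each replicate were chosen only after the result was seen. The cause of a change was not tested except where the construction of a setting shows it.

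For vinblastine after water (1005 genes) the donor block gave 4554, no filter 648, total scaling 1715 and a 2-fold threshold 341. The libraries compared alone gave 122 (2265 with the block), edgeR with the block 4500, DESeq2 2066 and DESeq2 with the block 4941. Without 1 replicate the count was 0 to 300. For vinblastine after ROCKi (523) the block gave 3206, a 2-fold threshold 222, the libraries compared alone 69 (1990 with the block), edgeR with the block 3176, DESeq2 1298 and DESeq2 with the block 3720. Without 1 replicate it was 0 to 263. The block removes the differences between donors from the error, which raises its counts by construction. Leaving out a replicate or the other groups removes degrees of freedom, which tends to lower the counts. This cannot explain why they differ with the replicate left out (97, 300 and 0 after water without replicate 1, 2 and 3). The cause of that difference was not tested.

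For ROCKi with DMSO (0) DESeq2 gave 10 and DESeq2 with the block 165. For the difference of responses (0) edgeR with the block gave 1, DESeq2 4 and DESeq2 with the block 58. Of those 58 genes 49 had an unadjusted p under 0.05 in the blocked limma fit and 6 had a 0 beside a value of at least 100 both among the libraries of a group and among those of a donor. For ROCKi with vinblastine (0) the block gave 208, the block with the libraries compared alone 68, edgeR with the block 182, DESeq2 68 and DESeq2 with the block 934.

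The lists past their test were 11 after water, 11 for ROCKi with DMSO, 9 after ROCKi, 4 for the difference and 9 for ROCKi with vinblastine. With an estimated correlation they were 0, 0, 0, 0 and 0, with the block and an estimated correlation again 0, 0, 0, 0 and 0, and with fry and the block 21, 0, 21, 0 and 4. Fry gave 0 for ROCKi with DMSO, 0 for the difference and 1 for ROCKi with vinblastine. Without 1 replicate the difference had 2 to 4 lists.

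The list median of microtubule-binding proteins after water, a list that camera called, changed sign. It was 0.069 as deposited, −0.031 with upper quartile and −0.117 with total scaling. Medians of some lists that did not pass changed sign as well. Some values of genes named here changed sign too, all in comparisons where the gene was not called. After water ARHGEF2 was −0.044 with total scaling, THBD 0.013 with edgeR, and RHOA −0.082 with upper quartile and −0.17 with total scaling. Without 1 replicate KLF2 was −0.37 to 1.02, RHOA −0.016 to 0.047 and THBD −0.18 to 0.22. In the difference of responses SELE was −0.25 to 1.75 and TUBA1B −0.096 to 0.083, and for ROCKi with vinblastine CXCL8 was −0.27 to 0.57.

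Of 48 genes named as called after water 44 were called with edgeR without a block, which lost CX3CL1, SELE, RIMS1 and GALNT15, and 47 with a pseudocount of 0.1, which lost DUSP8. Plain limma called 44 of them and lost MT-ND4L, PCNA, RIMS1 and GALNT15. Without replicate 1, 2 or 3, 12, 21 and 0 of the 48 kept their calls, and with the libraries compared alone 14. Of 24 genes named as called after ROCKi 8 kept their calls with the libraries compared alone, and 3, 12 and 0 without replicate 1, 2 or 3. There edgeR lost CX3CL1. The donor block took away the camera call of the list of microtubule-binding proteins after water, and its other changes of calls were additions. Every gene called without the block was called with it. The kept share (88.2%) was 78.7 to 94.4% over the alternatives run for it, a move of less than its SD. These were 50 or 500 genes of each sign, each sign alone, a pseudocount of 5, upper quartile and total scaling, the called genes and leaving out each replicate.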

Other observations

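The tests of gene families, of ROCKi against vinblastine and of values at 0 were chosen only after the result was seen, except that for GC content and length, which was planned before.

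Gene families were grouped by the stem of their symbols (477 with at least 5 tested members), and 4.45% of tested genes rose and 2.56% fell after water. GIMAP genes, which code for GTPases, fell in 5 of 7 members (6 with the donor block) with a median of −1.70, and 3 fell after ROCKi (6 with the donor block, median −1.39). GIMAP1, GIMAP4, GIMAP6 and GIMAP8 changed by −2.04, −1.72, −1.04 and −1.70 (adjusted p = 0.0172, 0.0347, 0.0169 and 0.0182). Genes with a DUSP symbol, which include dual-specificity phosphatases of several kinds and 1 pseudogene, rose in 6 of 19 (5 after ROCKi), with DUSP1, DUSP5 and DUSP16 at 1.53, 2.09 and 1.38 (adjusted p = 0.0174, 0.0399 and 0.000902). TNFAIP genes rose in 4 of 6 in both arms, with TNFAIP3, a brake on NF-kB, at 2.59 (adjusted p = 0.0259). HOXA genes, developmental transcription factors, fell in 2 of 10 after water and 0 after ROCKi (6 in each arm with the donor block), HOXA2 and HOXA5 at −1.76 and −1.74 (adjusted p = 0.0285 and 0.0315).

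With ROCKi alone, changes ran weakly against those with vinblastine (r = −0.06 and covariance −0.0147 over 14332 genes). The 3 shared control libraries alone would give a positive covariance (0.0546 in 20 simulated draws). The simulated r of 0.487 cannot be set against −0.06. Those draws held no response to treatment, and the variance of real responses lowers such an r. The change of a donor with vinblastine and the change of the other donors with ROCKi, which share no library, had r of −0.209 to −0.129. GC content and gene length are excluded as its source, because r was −0.259 to −0.11 once trends with both were removed (13412 genes). For comparison, the 2 responses to vinblastine had r of 0.396 to 0.485 between donors, and the difference of responses had 0.026 to 0.08 with itself.

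In 69 tested genes a value of 0 stood beside one of at least 100 among the 3 libraries of some group, and also among the 4 libraries of some donor. Of these 46 (66.7%) had no location in the annotation, against 913 (6.37%) of tested genes. In vinblastine after water, vinblastine after ROCKi and the blocked fit of ROCKi with vinblastine 0 of the 69 were called.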
